A study of Homo sapiens with 2 samples.

How the data were processed

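MDA-MB-231 cells received lentivirus carrying either a negative control or TRPC5OS, messenger RNA was enriched by poly(A) selection and libraries were made with a stranded kit, per the labels' protocols. GEO's labels give 2 samples, 1 per group, and groups were taken from the treatment label. The series text speaks of pairs of samples, but the labels used here hold 1 library per group. The submitters' processing notes name cutadapt, HISAT2 and StringTie; their versions, the genome build, the annotation and the strand setting of the quantification are not given in the sources used here.

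The authors deposited 6 tables: all genes, all transcripts, and the higher and lower genes and transcripts of their comparison. The deposited FPKM values are fragments per kilobase of transcript and 1000000 fragments, per the file headers, given per gene and per transcript. The columns whose header ends in FPKM hold log2(FPKM + 1) of the deposited FPKM columns in the same row, as checked in every row. The deposited log2 fold change is overexpressing minus control on that scale, and the deposited ratio, or fold change, is its antilog. The deposited p-values and q-values are 1 in every row of both full tables and carry no test result. All rows are typed as protein coding, and the higher of the 2 FPKM values in a gene's row is never under 0.50, so genes low in both libraries are not among the rows and the sum over rows is not the library's total. Gene values are not the sums of their transcripts' values.

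Depth could not be read from the values. In genes with 1 listed transcript, FPKM times transcript length would fall on whole multiples of a step if whole fragments had been counted; 26.5% of 117 low values in the control and 31.0% of 84 in the overexpressing library lay within 0.05 of a multiple of the best step, against 16.8% and 18.7% with transcript lengths shuffled. No interval or lower limit that needs depth is therefore given. In 108 genes the control, and in 72 genes the overexpressing library, is listed at 0; such a 0 can be a failed estimate and no fold is given against it for a single gene, though these genes enter the counts and medians through log2(FPKM + 1).

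With 1 library per group, no test was run between groups. Differences were taken on log2(FPKM + 1) among genes with a mean of at least 1 FPKM over both libraries, and a gene was counted when its log2 difference was at least 1 in size, a 2-fold change. For 37 gene lists, fixed before the data were examined, as were the sizes, filters and naming rule, the median difference of the measured members was set among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. A list with at least 5 measured members was said to stand apart under percentile 2.5 or over 97.5. The percentile describes these 2 libraries. List symbols missing from the tables were matched through gene identifiers. The text names TRPC5OS and ENO1, then the 12 highest and 12 lowest genes with a mean of at least 5 FPKM that passed the 2-fold size with pseudocounts of 1 and 0.1 and after median centring, then the 2 highest and 2 lowest members of a described list, though not all of these are printed for each list, and some genes that the rule selects are not reported here. Genes named beyond this rule are other members of a list, genes that overlap a named gene and the family members in the closing section, and they were chosen after their values were seen. Genes that overlap on opposite strands can share reads where quantification ignores strand, which concerns several named list members; overlap on the same strand was found among listed genes for EGLN3 (with SPTSSA), RRM2 (with AC007240.1), PFKFB4 (with UCN2) and MCOLN1 (with PNPLA6), besides those named in the results.

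The GC content and length of each gene were those of its longest coding transcript in GENCODE release 29 on GRCh38, matched by gene identifier; 98.9% of genes had a value. Only sequence properties were taken from that annotation: of 12190 genes matched by identifier outside the mitochondrial genome, 86 had the same start and end there, so the deposited coordinates belong to another build and are printed as deposited. The GC trend was the median difference in 40 bins of equal gene number, interpolated along GC content. Matching on expression and GC content used 10 bins of each. The sequence shared by a pair of transcripts was the share of 31-base words of the transcript with fewer that both held. The GC correction and this matching were chosen after the data were seen.

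Alternatives were pseudocounts of 0.1 and 0.5 FPKM, no filter, a mean of at least 5 FPKM, centring on the median of genes with a mean of at least 10 FPKM, rescaling each library to a sum of 1000000, gene values as sums of transcripts, unmatched random lists and the GC correction. The list percentiles, GC trend, neighbour correlation and slope were tested on simulated data. In 10820 genes with a simulated GC trend, 3.5% of unshifted lists of 20 genes fell outside the limits, 57.5% of lists shifted by 0.5 and 99.5% of lists shifted by 1. AT-rich lists with no shift fell outside in 36.0% of draws when matched on expression and in 4.0% when matched on both. Simulated genes varied independently and list members were drawn at random, so these rates do not cover lists whose genes vary together. Numbers of lists or families expected by chance rest on the same independence. Computations used Python with numpy, scipy, pandas and matplotlib, in versions 3.11.15, 2.4.6, 1.17.1, 2.3.3 and 3.10.9.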

Results

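RNA was sequenced from MDA-MB-231, an established human breast cancer cell line, after lentiviral delivery of either a negative control or TRPC5OS, a gene named for its place on the strand opposite the calcium channel gene TRPC5. The comparison asks how the transcriptome differs when TRPC5OS is overexpressed, and the study is known to have followed glucose uptake and the glycolytic enzyme ENO1. Each of the 2 groups had 1 library, so the differences have no replicate check, no p-value is given, and every statement describes these 2 libraries. The values were FPKM for 12261 protein-coding genes and 32688 protein-coding transcripts. They summed over genes to 211249 in the control library and 199006 in the overexpressing library, and the 10 most abundant genes took 12.6% and 11.9% of those sums. Sequencing depth is unknown. Differences are overexpressing minus control on log2(FPKM + 1), a scale that understates the change of low genes.

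TRPC5OS was the gene with the largest positive difference. It was at 0.0589 FPKM in the control library and 190 FPKM in the overexpressing library, a log2 difference of 7.49. The gene (ENSG00000204025.7_3) lies on the plus strand of chromosome X from 111119279 to 111147218, in the coordinates of the deposited files, whose build is not given in the sources used here. Of its 3 listed transcripts, TRPC5OS-201 was at 0.0633 FPKM in the control and 172 FPKM in the overexpressing library, TRPC5OS-202 at 0 and 83.3 FPKM, and TRPC5OS-203 at 0 and 2.76 FPKM. TRPC5 was not among the listed genes, so no value is given for it. ENO1 (ENSG00000074800.13_3, chromosome 1, 8921061 to 8939308), which converts 2-phosphoglycerate to phosphoenolpyruvate in glycolysis, was at 666 FPKM in the control and 396 FPKM in the overexpressing library, a log2 difference of -0.75.

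With a pseudocount of 1 FPKM, KISS1 was the gene furthest above the control after TRPC5OS; with 0.1 FPKM, ENG, VSTM1 and NPPB came before it. KISS1, which encodes the kisspeptin precursor and was first described as a metastasis suppressor (ENSG00000170498.8_2, chromosome 1, 204159469 to 204165614), was at 0.676 FPKM in the control and 70.5 FPKM in the overexpressing library, 104-fold higher. ENG, encoding the TGF-beta co-receptor endoglin, was at 0.0521 and 26.9 FPKM, and the ubiquitin ligase gene MARCH4 at 0.382 and 20.6 FPKM. NPPB, encoding B-type natriuretic peptide, and the immune receptor gene VSTM1 were listed at 0 in the control and at 11.2 and 11.3 FPKM in the overexpressing library. With gene values as sums of transcripts, the log2 difference of VSTM1 was 1.94 instead of 3.62, so its size and rank are uncertain. That of NPPB was 3.61 either way. PTGFRN was at 0.0364 and 11.3 FPKM, the adhesion receptor gene ADGRG6 at 1.02 and 20.4 FPKM, the cystine transporter gene SLC7A11 at 0.696 and 15.1 FPKM, and the collagen gene COL8A1 at 2.97 and 36.7 FPKM. Reads of overlapping genes on the same strand cannot be assigned with certainty for the other 2 genes of this group. The read-through gene BLOC1S5-TXNDC5 was at 3.64 and 141 FPKM, while TXNDC5 itself, at 16.6 FPKM in the overexpressing library, had a log2 difference of -2.48. HNRNPH2 was at 0.692 and 31.8 FPKM, and the overlapping RPL36A-HNRNPH2 at 17.0 and 10.3 FPKM.

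The gene furthest below the control was CST1 with a pseudocount of 1 FPKM and CST4 with 0.1 FPKM. CST1, a secreted cysteine protease inhibitor (ENSG00000170373.8_2, chromosome 20, 23728190 to 23731905), was at 954 FPKM in the control and 0.531 FPKM in the overexpressing library, a log2 difference of -9.28. Its neighbours CST4 and CST2 were at 527 and 82.8 FPKM in the control and listed at 0 in the overexpressing library; the 3 genes are close paralogs that can share reads, so their separate values are uncertain. The mucin genes MUC5AC and MUC5B were at 67.1 and 34.4 FPKM in the control, and S100P and AGR2, an endoplasmic reticulum protein needed for mucin production, at 48.6 and 30.1 FPKM; all 4 were listed at 0 in the overexpressing library. SPDEF, a transcription factor of secretory epithelia, was at 45.4 FPKM in the control and 0.0319 FPKM in the overexpressing library, and the keratin gene KRT19 at 150 and 2.33 FPKM. The metalloprotease gene ADAM8 was at 94.7 and 0.501 FPKM, and the metalloprotease inhibitor gene TIMP3 at 157 and 2.78 FPKM.

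Of the 10890 genes with a mean of at least 1 FPKM, 1432 were at least 2-fold higher in the overexpressing library and 845 at least 2-fold lower, so that 62.9% of these genes were on the higher side. The differences moved with GC content. They were highest in AT-rich genes, with a median of 0.85 in the tenth of genes with the lowest GC content and -0.26 in the tenth with the highest, and Spearman's rho between difference and GC content was -0.43 across 10820 genes, which are not independent replicates. With the median difference along GC content removed, which centres the differences at 0 at every GC content, 838 genes were at least 2-fold higher and 856 lower. Of the 1432 higher genes 711 stayed past that size, and of the 845 lower genes 680 did. The median difference over the 10890 genes was 0.10, and over the 4109 genes with a mean of at least 10 FPKM it was -0.02.

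**Figure D1:**
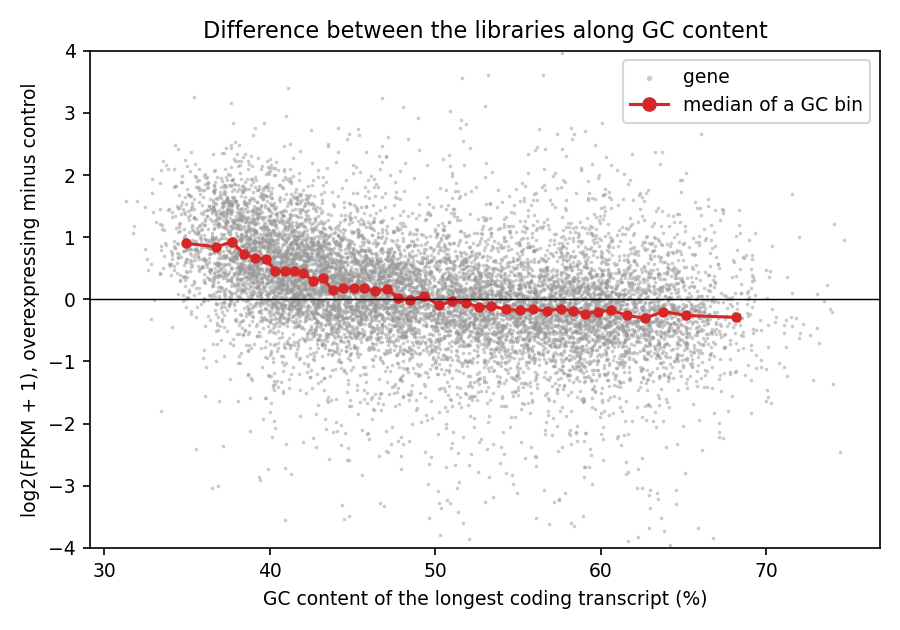
Difference in log2(FPKM + 1) between the overexpressing and the control library (vertical axis) against the GC content in percent of each gene's longest coding transcript (horizontal axis). Grey points are genes, 29 of which lie beyond the axis at 4 and -4, and red points are medians of 40 bins of GC content, which lie highest in AT-rich genes.

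Glycolytic enzymes and genes that cells induce in low oxygen were lower together in the overexpressing library. Of 17 glycolytic enzymes, 8 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 difference of -0.79. LDHA, which makes lactate, was at 267 FPKM in the control and 67.4 FPKM in the overexpressing library, and PGK1 at 247 and 64.2 FPKM; at the other end, HK1 was at 54.5 and 63.6 FPKM and LDHB at 163 and 164 FPKM. Of 22 hypoxia-induced genes, 11 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -1.07. The angiogenic factor gene VEGFA was at 37.6 and 3.70 FPKM and the prolyl hydroxylase gene EGLN3 at 9.72 and 0.946 FPKM, while BNIP3L was at 16.7 and 23.2 FPKM and P4HA2 at 11.0 and 8.59 FPKM. The glycolytic median lay at percentile 0.04 of 10000 random lists matched on expression, and the hypoxia median lay below all 10000. Their medians with the GC trend removed were -0.67 and -1.32.

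**Figure D2:**
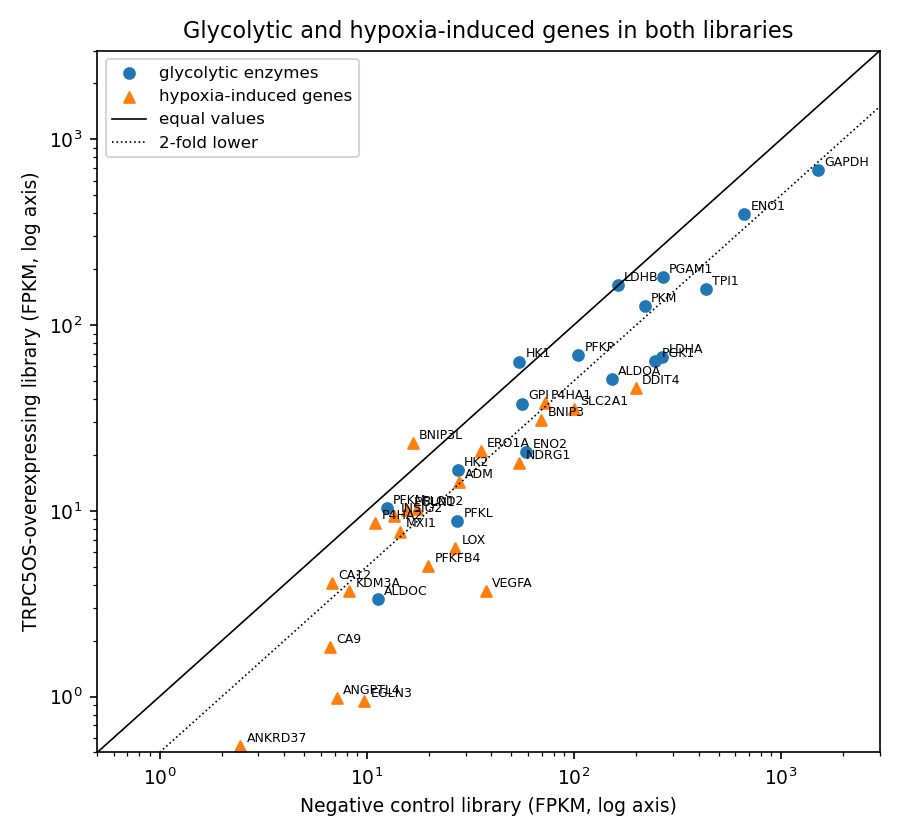
FPKM of the 17 glycolytic enzymes (circles) and 22 hypoxia-induced genes (triangles) in the control library (horizontal axis) and the overexpressing library (vertical axis), 1 library each, on log axes. The solid line marks equal values and the dotted line a 2-fold lower value; 15 of the 17 glycolytic enzymes and 21 of the 22 hypoxia-induced genes lie below the solid line, and LDHA, PGK1 and VEGFA lie below the dotted line.

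Genes of the pentose phosphate, hexosamine and serine pathways were higher. Among 18 of them, 6 were at least 2-fold higher and 1 lower, with a median of 0.63 at percentile 99.9. PSAT1, of serine synthesis, was at 33.7 FPKM in the control and 109 FPKM in the overexpressing library, and the pentose phosphate gene RPE at 3.37 and 13.2 FPKM; GFPT2 was at 38.8 and 15.9 FPKM and PGLS at 22.6 and 12.1 FPKM. The 16 measured genes of glucose and lactate transport and its regulation had a median of -0.02 and lay inside the range of random lists, at percentile 24.5, but the median of the 6 with a mean of at least 5 FPKM was -1.44, at percentile 0.04. The 16 went both ways: the lactate exporter gene SLC16A3 was at 55.9 and 16.2 FPKM and PFKFB4 at 19.8 and 5.03 FPKM, whereas ARRDC4 was at 1.01 and 6.45 FPKM and PDK3 at 0.992 and 5.31 FPKM. The 20 tricarboxylic acid cycle genes had a median of 0.32 at percentile 97.1, with IDH3A at 3.94 and 15.4 FPKM, and the 27 nuclear-encoded respiratory chain subunits a median of -0.07 at percentile 45.4.

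Inflammatory, interferon-stimulated and growth-factor response genes were lower in the overexpressing library. Of 22 NF-kB and inflammatory cytokine genes, 10 were at least 2-fold lower and 3 higher, with a median of -0.97. The cytokine genes IL6 and CSF2 were at 50.0 and 124 FPKM in the control and 3.40 and 11.2 FPKM in the overexpressing library, while IL11 was at 11.2 and 60.7 FPKM and TNFAIP3, an inhibitor of NF-kB signalling, at 3.65 and 10.3 FPKM. Of 25 interferon-stimulated genes, 9 were at least 2-fold lower and 0 higher, with a median of -0.85. The antiviral membrane protein gene BST2 was at 107 and 3.12 FPKM and OASL at 41.8 and 4.55 FPKM; IFI6 was at 10.6 and 19.4 FPKM and DDX60 at 5.25 and 9.67 FPKM. Of 23 immediate early and MAPK feedback genes, 8 were at least 2-fold lower and 1 higher, with a median of -0.78. DUSP4, a MAPK phosphatase, was at 165 and 14.5 FPKM and PHLDA1 at 133 and 12.5 FPKM, whereas DUSP1 was at 17.9 and 44.6 FPKM. The medians of these 3 lists lay below all 10000 random lists. Of 17 antigen presentation genes, 4 were at least 2-fold lower and 1 higher, with a median of -0.59 at percentile 0.1; PSMB10 was at 11.4 and 3.06 FPKM, HLA-DRA at 12.4 and 3.67 FPKM and HLA-F at 0.698 and 2.69 FPKM.

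Luminal breast markers showed the lowest median of the lists with at least 5 measured members, -2.97, below all 10000 random lists, and the list divided into genes low in the overexpressing library and genes at similar values in both. Of the 15 markers written for this list, 11 were listed. ESR1, PGR, FOXA1 and ANKRD30A were not among the listed genes of either library, so the median describes only the 11. KRT19, SPDEF and MLPH were at least 2-fold lower, and AGR2, TFF1 and TFF3, at 30.1, 10.4 and 7.71 FPKM in the control, were listed at 0 in the overexpressing library. The other 5 of the 11 were in neither group: the simple keratin genes KRT8 and KRT18 were at 46.1 and 68.1 FPKM in the control and 41.9 and 54.2 FPKM in the overexpressing library, XBP1 at 25.7 and 18.9 FPKM, GATA3 at 1.27 and 1.11 FPKM and ERBB3 at 0.932 and 1.51 FPKM. The 13 epithelial junction and keratin genes, which share KRT8, KRT18 and KRT19 with that list, had a median of -0.33 at percentile 5.71. The list stood apart as lower with no filter (percentile 0.43) and, at a median of -1.14, among the 9 members with a mean of at least 5 FPKM (0.03). JUP, encoding plakoglobin, was at 69.0 and 10.5 FPKM, whereas DSP, encoding desmoplakin, was at 11.3 FPKM in the control with a log2 difference of 1.13, and EPCAM at 2.61 and 6.12 FPKM. Of 5 measured basal or myoepithelial markers, 2 were at least 2-fold lower, among them ITGB4 at 64.4 and 4.72 FPKM, and the median of -0.54 lay at percentile 5.48.

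Matrix and mesenchymal genes were split. Of 19 matrix remodelling genes, 7 were at least 2-fold lower and 3 higher, with a median of -0.32 at percentile 5.43, and the list stood apart as lower with no filter (2.49) and with unmatched random lists (1.59). The membrane metalloprotease gene MMP14 was at 265 FPKM in the control and 22.7 FPKM in the overexpressing library, whereas the secreted protease genes MMP3 and MMP9 were at 0.242 and 0.0992 FPKM in the control and 6.83 and 2.60 FPKM in the overexpressing library. Of 16 mesenchymal genes, 6 were at least 2-fold higher and 3 lower, with a median of 0.22 at percentile 89.7. The transcription factor gene SNAI1 was at 0.859 and 11.5 FPKM, while the fibronectin gene FN1 was at 145 and 14.1 FPKM and COL6A1 at 41.5 and 12.1 FPKM. Among 18 TGF-beta and BMP target genes, 6 were at least 2-fold lower and 4 higher, and the median of -0.53 lay at percentile 0.18. CTGF, at 48.0 and 330 FPKM, was among its 2 highest members, and BMP4, at 31.9 and 5.34 FPKM, and TGFBR2, at 164 and 39.0 FPKM, were its lowest. Of 12 Wnt target and feedback genes, 5 were at least 2-fold lower and 1 higher, with a median of -0.43 at percentile 1.16, but the list lay inside the range with transcript sums (10.2) and at a mean of at least 5 FPKM (4.58). MYC was at 23.6 and 2.94 FPKM, LGR5 at 3.90 and 0.115 FPKM, and the Wnt inhibitor gene DKK1 at 20.4 and 117 FPKM.

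Targets of YAP and TEAD, oxidative stress genes and cell-cycle genes were higher in the overexpressing library. Of 19 YAP and TEAD target genes, 7 were at least 2-fold higher and 1 lower, with a median of 0.77 above all 10000 random lists. CTGF was at 48.0 FPKM in the control and 330 FPKM in the overexpressing library and CRIM1 at 23.4 and 96.5 FPKM, with FJX1 at 39.8 and 16.5 FPKM. Of 17 NRF2 genes, 5 were at least 2-fold higher and 1 lower, with a median of 0.62 at percentile 99.9. The glutathione synthesis gene GCLM was at 6.13 and 29.6 FPKM, SLC7A11 at 0.696 and 15.1 FPKM, and the ferritin gene FTH1 at 377 and 163 FPKM. Of 28 genes of mitosis and G2/M, 7 were at least 2-fold higher and 0 lower, with a median of 0.59 above all 10000 random lists and 0.43 with the GC trend removed. The cytokinesis gene ANLN was at 19.1 and 95.1 FPKM and the kinetochore gene CENPF at 8.62 and 39.3 FPKM, while FOXM1 was at 20.7 and 14.0 FPKM and PLK1 at 19.1 and 17.8 FPKM. Of 31 genes of DNA replication, 4 were at least 2-fold higher and 0 lower, with a median of 0.32 at percentile 98.8, though inside the range of unmatched random lists (90.8). RRM2, which makes deoxyribonucleotides, was at 11.4 and 63.0 FPKM and POLA1 at 2.61 and 13.2 FPKM.

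Of the 37 gene lists fixed before the data were examined, 32 had at least 5 measured members, and 15 of these 32 stood apart. By chance 1.6 would be expected if genes varied independently, which the genes of a list need not do. Of the 15 lists, 10 were lower and 5 higher. The same 15 stood apart when random lists were also matched on GC content, where apoptosis regulators joined them on the lower side (median -0.16; percentile 5.9 matched on expression, 2.4 matched on both). The list of 9 TRP channel genes had a median of -0.51 at percentile 0.79, and is counted among the lower lists although 2 members were at least 2-fold higher and 1 lower. MCOLN1 was at 9.33 and 3.46 FPKM, whereas TRPM7 was at 1.02 and 5.31 FPKM. Lists inside the range included p53 targets (median 0.21), ATF4 targets (0.09), the unfolded protein response (0.20), heat shock proteins (0.03), sterol synthesis (0.32) and fatty acid synthesis (0.17). Of these, sterol synthesis (percentile 99.4) and the unfolded protein response (97.6) stood apart as higher among members with a mean of at least 5 FPKM. Single members of these lists were far from their medians. GDF15, a p53 target, was at 17.7 and 1.11 FPKM, ASNS, an ATF4 target, at 5.18 and 29.7 FPKM, the sterol transport gene STARD4 at 1.29 and 11.8 FPKM, and HSP90AA1 at 121 and 401 FPKM.

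**Figure D3:**
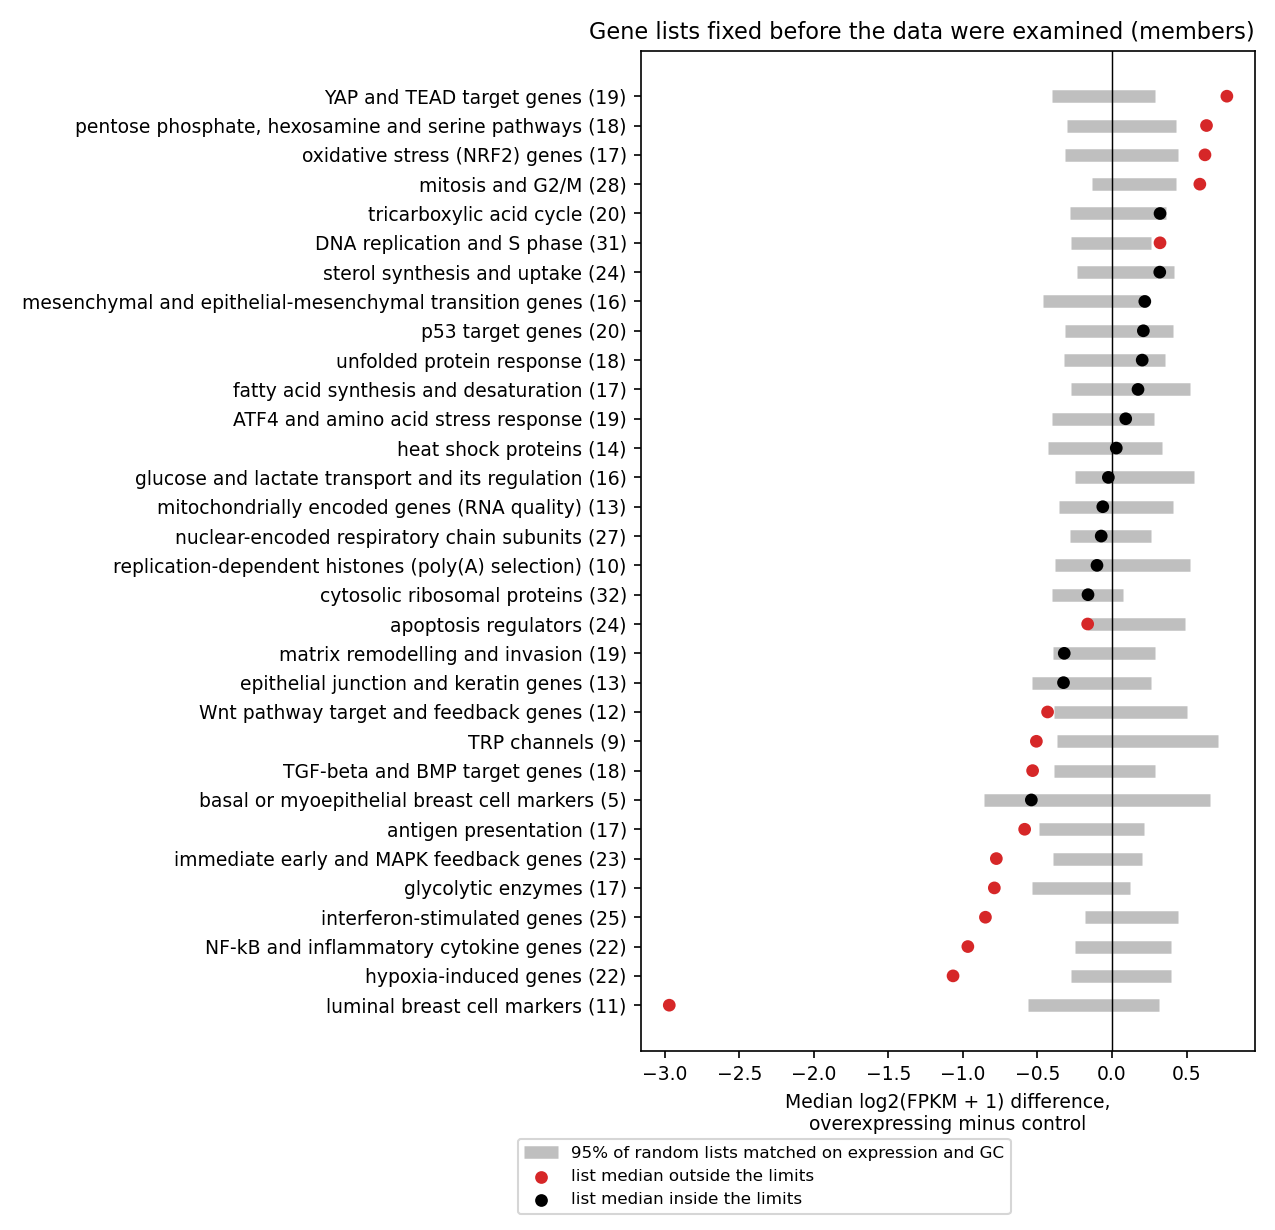
Median difference in log2(FPKM + 1), overexpressing minus control, of 32 gene lists, with the number of measured members after each name. Grey bars span 95% of 10000 random lists matched on expression and GC content, red points lie outside the limits and black points inside; the luminal marker list lies lowest, at -2.97, and the YAP and TEAD target list highest, at 0.77.

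Markers of other cell types and of RNA handling were measured alongside. Of 3 leukocyte markers with a mean of at least 1 FPKM, LAPTM5 was at 67.4 FPKM in the control and 23.7 FPKM in the overexpressing library, CD68 at 44.6 and 16.9 FPKM, and CORO1A at 0.374 and 2.70 FPKM. With no filter, 5 such markers could be tested and stood apart as lower, with a median of -0.95 at percentile 0.48, as they did with transcript sums (0.715). Of 4 fibroblast and endothelial markers, too few for a percentile, 3 were at least 2-fold higher and 0 lower, with a median of 1.07: PDGFRB was at 0.505 and 4.25 FPKM, KDR at 1.29 and 3.95 FPKM, ACTA2 at 0.827 and 2.71 FPKM and COL1A1 at 1.06 and 1.56 FPKM. Markers of the HEK293 lineage, from which lentivirus is commonly packaged, were at similar values, with SIX2 at 3.89 and 4.80 FPKM. Medians were -0.16 for 32 cytosolic ribosomal proteins, -0.10 for 10 replication-dependent histones and -0.06 for 13 mitochondrially encoded genes, and each lay inside the range of random lists. With the GC trend removed the mitochondrially encoded genes had a median of -0.57, which was not ranked. Their median of -0.06 lay inside the range of random lists matched on expression and GC content, at percentile 36.0. Of 4 cancer/testis antigen genes, SPANXB1 was at 28.1 and 0.802 FPKM, and CT83 at 4.95 and 3.84 FPKM.

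At the level of transcripts, 3863 of the 21784 transcripts with a mean of at least 1 FPKM were at least 2-fold higher in the overexpressing library and 3291 at least 2-fold lower. Among the transcripts listed at 0 in 1 library and at 10 FPKM or more in the other, 176 belonged to listed genes with a single row, and for 84 of them the gene itself differed by less than 1.5-fold. The authors' deposited tables held 3269 higher and 1987 lower genes, all at least 1.5-fold apart on the same scale, and 9009 higher and 7569 lower transcripts. Of those genes, 1432 of the higher and 845 of the lower also met the 2-fold size and the mean of at least 1 FPKM used here. Both selections cut the same values on the same scale, so this overlap follows from the thresholds.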

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

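The GC correction and GC-matched lists were chosen after the data were seen, and the other alternatives beforehand. The count of genes at least 2-fold higher, 1432 as reported, was 754 among genes with a mean of at least 5 FPKM, where fewer genes were tested, 2149 after rescaling each library to a sum of 1000000, which shrinks the pseudocount against the values and moves the median difference from 0.10 to 0.20 (their shares were not separated), and 838 with the GC correction, which takes the trend out of AT-rich genes. The 845 lower genes stayed within 1.5 times under all 8 alternatives, from 571 to 1085. Transcript counts were 1540 higher and 1479 lower at a mean of at least 5 FPKM, where fewer were tested, and otherwise within 1.5 times. For TRPC5OS the log2 difference of 7.49 was 10.22 with a pseudocount of 0.1 FPKM, since its control value is near 0, and 6.71 with the GC correction, and within 1.5-fold of it under the other 2. The number of lists that stood apart, 15 as reported, was 15 to 18, and 13 of the 15 stood apart in each of the 7 settings that could test them. Wnt targets and DNA replication did not, and TRP channels had under 5 members at a mean of at least 5 FPKM. No called value changed sign, and 22 of 94 alternative values of the other named genes moved by over 1.5-fold. BLOC1S5-TXNDC5 had no GC-corrected value. With 1 library per group, neither depth nor the spread between cultures is known, and this limits every value here. No paired analysis was possible because each group had 1 library.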

Other observations

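The gene families, the slope between transcripts, its repeat in pairs that share little sequence, the test within lengths, the hypoxia list without glucose genes, the correlations at 50 and 100 places, the comparison with local clusters and the chromosomes outside once more trends were removed were chosen only after the results were seen. Among 179 families of genes with a shared symbol stem and at least 8 measured members, 2 lay above and 11 below the limits. These limits came from random lists matched on expression and GC content. By chance 8.95 would lie outside if genes varied independently, so single families other than the extreme ones carry little weight. The CEP genes, most of which encode centrosome proteins, lay above all 10000 random lists: 15 of 30 were at least 2-fold higher and 0 lower, with a median of 0.97, or 0.51 with the GC trend removed. CEP152, needed for centriole duplication, was at 0.659 FPKM in the control and 4.17 FPKM in the overexpressing library, and CEP295 at 0.624 and 3.75 FPKM. At the other end were 28 genes whose symbols start with CD, mostly named as cell-surface antigens and not as relatives, with a median of -0.48 at percentile 0.04; 6 were at least 2-fold lower and 5 higher. CD82 was at 38.8 and 11.8 FPKM and CD40 at 5.29 and 14.7 FPKM. Next were 11 CHMP genes, which encode subunits of the membrane-cutting ESCRT-III complex, with a median of -0.64 at percentile 0.17.

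Differences fell with GC content across genes, and the trend was steepest in AT-rich genes. Gene length is not the whole cause, since within 10 bins of transcript length the median rho between difference and GC content was still -0.41, and it ran from -0.60 to -0.20. Whether a bias in how fragments of different GC content were amplified or sequenced is the whole cause was not decided. Between the 2 most abundant transcripts of 5539 genes rho was -0.052 (bootstrap 95% interval -0.075 to -0.026). This was nearer 0 than the bound of -0.1 set beforehand. It was also nearer 0 than the range of -0.133 to -0.0853, around that bound, that the full trend acting on transcripts gave in simulation. These values argue against the full trend acting on each transcript as a whole. A bias on fragments would act alike on sequence that both transcripts hold, a median of 94.7% per pair, which the simulation left out. Such bias could account for part, since the differences between transcripts followed the trend with a slope of 0.40 (0.19 to 0.60). The slope was 0.40 (-0.02 to 0.83) in the 349 pairs sharing less than 50% of their sequence. Those pairs can still share exons and their interval includes 0, so shared exons as a reason for a slope under 1 stay open. A response of AT-rich genes to TRPC5OS stays open and was not tested.

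Glycolytic and hypoxia-induced genes were lower together in the overexpressing library. The GC trend does not account for this, since the 39 genes of both lists had a median of -0.97 that went to -1.24 with the trend removed, below all 10000 random lists matched on expression and GC content. The lower values were not confined to genes of glucose metabolism, because the 20 hypoxia-induced genes outside it had a median of -1.29 with the trend removed, again below all 10000. These 20 are most of the same 22 genes, whose median was already -1.32, so this restates the list and is no separate test. A weaker hypoxia-type response in the overexpressing culture is a candidate explanation, a hypothesis from these same data that was not tested separately. Cell density and oxygen at harvest, which can set such a response and are not recorded in the sources used here, cannot be separated from TRPC5OS with 1 culture per group, were not tested, and stay open.

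Differences were shared along chromosomes. With the GC trend removed, the median was 0.37 over 340 genes of chromosome 15 and -0.24 over 564 genes of chromosome 12, and 6 of 23 chromosomes lay beyond the extremes that 95% of shuffled gene orders gave. Shuffled orders break up the correlation of close neighbours, so local clusters alone could place chromosomes outside such limits. The counts of chromosomes outside, here and below, therefore do not separate local from chromosome-wide differences. Whether local gene clusters are the whole cause was not decided. Genes 50 places apart had a Pearson's r of 0.036, against 0.17 for adjacent genes. The value at 50 places was small but above the 0.032 that was the highest of 1000 shuffled orders. At 100 places r was 0.0217, at percentile 97.7 of shuffled orders. Shuffled orders hold no local correlation, so their range can be too narrow to exclude local clusters. Trends with surrounding GC content, length and expression level, as removed here, accounted for little of r at 50 places. It was 0.0330 once they were removed, barely above the 0.0328 that was then the highest of the shuffled orders. The same limit of shuffled orders applies. At 100 places r was then 0.0179, inside the shuffled range at percentile 95.4. Of the 6 chromosomes only 12, 2 and 15 stayed outside, with 5 outside in all. Different copy number in the 2 cultures, as between diverged clones of this line, may contribute, which would be present whatever TRPC5OS does; this is a hypothesis found in the same data, and a domain-wide response to TRPC5OS stays open.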
